A study of Mus musculus with 4 samples.

How the data were processed

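GR was immunoprecipitated from differentiated CD137+ and PDGFRa+ adipose progenitors of C57BL/6 mice given dexamethasone, with 1 immunoprecipitate and 1 input per cell type. Per the labels' protocols, the cells were isolated by magnetic sorting from tissue abbreviated as SAT or VAT, with no statement of which tissue gave which cells, and were exposed to an adipogenic cocktail. The extraction protocol in the labels mentions embryonic cells and removal of the zona pellucida, which does not match the adipose source given in the same labels, so the lysis and shearing steps are taken as unknown. The submitters' processing notes name FastQC, Bowtie2, MACS2, SAMtools, bedtools 2.17.0 and the mm10 build, with no role, setting or threshold. Whether the inputs were used in peak calling, and the read depth of each library, are not given in the sources used here. The inputs were not analysed here by themselves.

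The 2 deposited tables differ in kind. The CD137+ table has a line per gene for 30 genes and, per the file headers, gives for each the called intervals of both libraries, a flag for a CD137+ interval, the distance to the gene start, and peak values. The deposited peak values are a signal of each interval in a unit that no header explains, given as the mean over the gene's CD137+ intervals and as the highest value with the library that holds it. All 30 genes carry the CD137+ flag, so the table was limited to genes with a CD137+ interval. All 23 interval positions are multiples of 16 bp. Its column names carry mm10 and a read length of 75. The PDGFRa+ list has 10402 peaks with the column layout of the annotation tool of HOMER, which the file does not name. The deposited peak score is a whole number from 20 upwards whose scale is not stated, and the list gives neither a q value nor an enrichment. The 5 most frequent scores hold 73.5% of the peaks, and 71.9% of the peaks have the least width, 146 bp. For 1 peak the end was not a number, and 1 peak had no nearest gene. Peaks of the list are named for that library alone, and both scores and signal values were used here only to describe and rank within their own table.

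The build of the PDGFRa+ list was checked against the gene table of the mouse assembly GRCm38.p6, which corresponds to mm10. The start sites implied by each peak and its stated distance lay within 1 kb of the gene's end in that table for 610 of 10347 peaks (5.90%), with a median offset of 169568 bp. Chromosome 16 held 311 of these 610, from 428 peaks, and the other chromosomes 299. On 9 chromosomes, 62 peaks lay beyond the last gene. In the CD137+ table, 22 of the 29 genes found in the gene table lay within 1 kb. The PDGFRa+ coordinates are therefore taken to be on another build than the labels state, whose positions on much of chromosome 16 are close to those of GRCm38, and are printed as deposited. No coordinate was converted, and the gene table served for names, lengths and neighbours. Of the 6081 Entrez gene identifiers, 6070 were found in it. No genome sequence was used, so a search for the GR binding motif was not analysed here.

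An overlap of coordinates had been planned. Since the builds differ, a CD137+ interval was instead counted as shared when a PDGFRa+ peak lay within 500 bp of the same distance from the start of the same gene or a neighbouring gene, a rule chosen after seeing the data. Chance sharing came from 10000 random placements of the intervals along their own chromosomes. Placements ran from the first to the last protein-coding gene and were not limited to genes. Shares of peaks per annotation class, as the list annotates them, have 95% Wilson intervals that cover counting error only. No p-value was computed between cell types, because each has 1 library.

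The 19 gene lists, the groups, the rule for named genes and the first set of alternatives were fixed before the data were examined. A listed gene counted if at least 1 peak, at any distance, named it as nearest gene. The count was ranked among 10000 random lists of protein-coding genes of the same size, drawn from the 100 neighbours in gene length rank on either side, with ties counted at their midpoint. Of the 20953 protein-coding genes, 23.5% had a peak. Listed names were matched by gene identifier and synonym. Percentile 97.5 was the threshold, and 19 lists were ranked for each table. On simulated data, 20 of 20 lists with planted peaks and 0 of 20 lists without reached it. Planted genes drew peaks with a weight of 4 against 1, and weaker planting was not simulated. Simulated peaks were drawn gene by gene according to gene length, and lists without planting were random genes. Gene territory, intergenic peaks and the choice of listed genes were thus not simulated, so the 0 of 20 does not measure false calls from these. Of simulated sites, 160 of 160 planted and 3 of 300 random sites were counted as shared. Planted sites lay within 200 bp of a listed peak's position, so the 500 bp rule had to find them. How many real shared sites the rule misses was not measured.

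Named in the text are every interval of the shorter table, the 15 genes with the highest peak score on an autosome or X in the longer list (predicted genes skipped), up to 4 members of each list by highest score with ties in the order of the deposited peak list, and Tead1, Tnfrsf9, Pdgfra, Nr3c1, Fkbp5, Tsc22d3 and Per1. Some genes are not reported here. The score took the place of the enrichment, as the rule allows. Listed genes named as having no peak, beyond these 7, were chosen after their values were seen. Alternatives were restriction to autosomes and X, wider or narrower windows for shared sites and promoters, and random lists without matching. Added after seeing the data were a 200 bp window for shared sites, a score of at least 50 and peaks within 100 kb. Matching on gene territory (the gene with the gaps to its neighbours) was added then too. So was removal of peaks annotated to satellite, rRNA, simple repeat or low complexity sequence. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.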

Results

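The glucocorticoid receptor (GR), the nuclear receptor that binds glucocorticoid hormones, was mapped by chromatin immunoprecipitation and sequencing in adipose progenitors of C57BL/6 mice. Cells carrying CD137, the receptor encoded by Tnfrsf9, or PDGFRa, a receptor for platelet-derived growth factor used as a marker of fat cell progenitors, were differentiated and given the synthetic glucocorticoid dexamethasone at 1 µM. The series holds 4 libraries, with 1 GR immunoprecipitate and 1 input for each cell type. The title of the series links glucocorticoids, PDGFRa+ cells and the methylation state of Tead1, so the design asks where GR lay in each of the 2 progenitor types. No group had a replicate, so no difference between cell types has a replicate check, and the read depth of the libraries is unknown. The CD137+ values came as a gene table of called intervals, and the PDGFRa+ values as a list of 10402 peaks on another genome build. The CD137+ table listed 23 intervals, and since the tables differ in format and build, these counts are not read as a comparison of the cell types.

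In CD137+ cells, GR intervals lay at known glucocorticoid target genes. An interval stood 1900 bp upstream of Per1, a clock gene induced by glucocorticoids (chromosome 11, position 69097056, mm10), with a peak value of 52. Fkbp5, which encodes a co-chaperone of GR and is induced by it, held an interval 65760 bp into the gene with a value of 33 (chromosome 17, 28420352). The strongest interval of the table, with a value of 74, stood 32064 bp upstream of the Fkbp5 start site, next to LOC100862287 and E230001N04Rik. Zbtb16, a zinc finger transcription factor gene, held an interval 112265 bp into the gene with a value of 31 (chromosome 9, 48723680). Of the 30 genes of the glucocorticoid response list, 3 were in the CD137+ table (Per1, Fkbp5 and Zbtb16), against 0.0366 for random lists matched on gene length. That count was at percentile 100 of 10000 such lists. The circadian clock list had Per1 alone among its 19 genes, at percentile 98.5, and none of the other 17 lists had a member in the table. Random lists matched to these 17 averaged at most 0.0531 members. A count of 0 was therefore likely for each and is no sign of specificity.

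The 23 CD137+ intervals were assigned to 30 genes, with 17 intervals inside a gene and 6 outside. Peak values ran from 28 to 74 in the authors' unit, with a median of 41.5. After the interval upstream of Fkbp5 (chromosome 17, position 28518176, mm10), the highest values were 67 in Klf13 (chromosome 7, 63897088), 65 in Apbb2 (chromosome 5, 66572608) and 60 in Tenm4 (chromosome 7, 96713056). Klf13 encodes a zinc finger transcription factor, Apbb2 a protein that binds the amyloid precursor protein, and Tenm4 a teneurin of the cell surface. An interval with a value of 57 lay downstream of the agouti gene (a) and of Ahcy, the hydrolase of S-adenosylhomocysteine (chromosome 2, 155052832). A230028O05Rik had an interval 247 bp upstream with a value of 56. Pibf1 and the interval between Gm16325 and 4930503B20Rik had values of 49 each.

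Foxp1, a forkhead transcription factor gene, had a value of 42 (chromosome 6, 99175616), and Zhx3, a zinc finger and homeobox gene, a value of 40 (chromosome 2, 160805312). Hif3a, which encodes a hypoxia-inducible factor subunit, held an interval 4107 bp into the gene with a value of 37 (chromosome 7, 17058320). The tensin genes Tns1 and Tenc1 had intervals with values of 42 and 34, the former inside the gene and the latter 332 bp upstream of Tenc1 and downstream of Eif4b. Cblb, a ubiquitin ligase gene, had a value of 39. Ddc, the gene of aromatic amino acid decarboxylase, held 2 intervals with a mean value of 41.5. The remaining intervals were those at 2310002D06Rik and Galnt16 (41), Myo1h and Kctd10 (37), Cdr2 and 4933427G17Rik (30) and 4930486L24Rik (28). Tead1, Pdgfra, Nr3c1, Tsc22d3 and Tnfrsf9 were not among the 30 genes. The table lists only genes with a CD137+ interval, and 13 interval numbers of the CD137+ library are not among its entries, so a gene missing from it is not shown to be unbound.

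**Figure D1:**
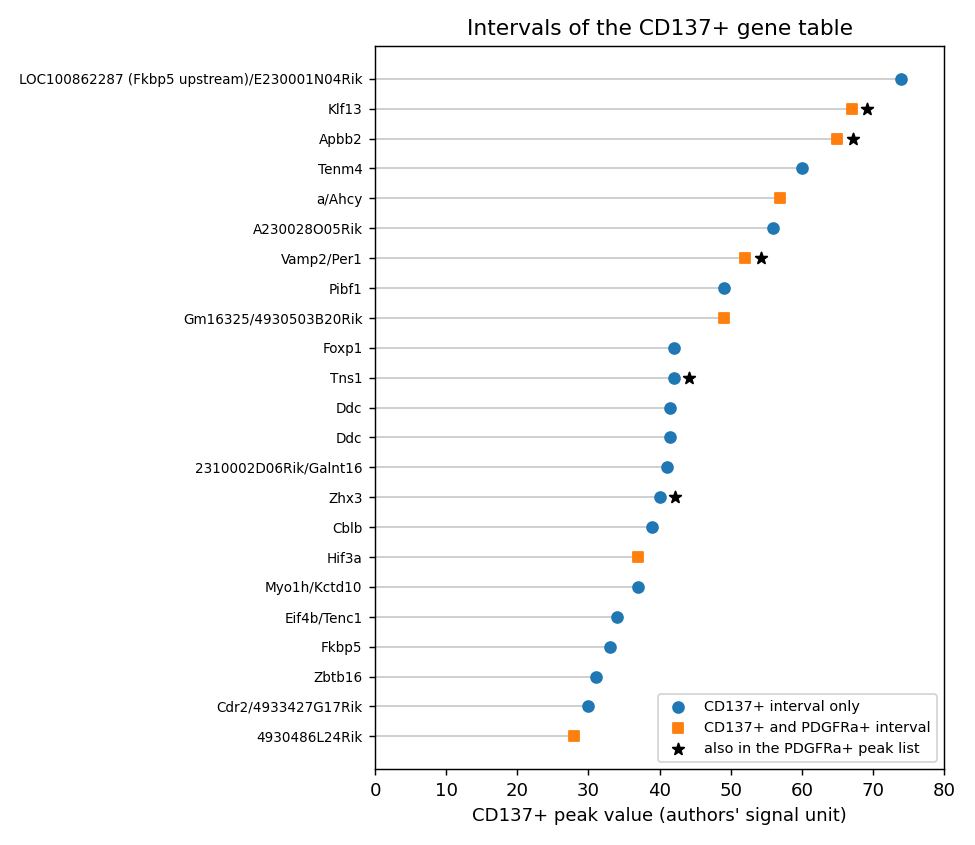
Peak value in the authors' signal unit (x axis) of each of the 23 CD137+ GR intervals, by the gene or genes assigned (y axis; the 2 Ddc intervals carry their mean). Squares are the 7 intervals with a PDGFRa+ interval in the same table, and stars the 5 with a peak in the PDGFRa+ list; the interval upstream of Fkbp5 has the highest value, 74.

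The CD137+ table also names PDGFRa+ intervals. Its entries were all selected for a CD137+ interval, so a site with a PDGFRa+ interval alone cannot appear, and the counts of this table lean towards CD137+ by construction. At 7 of the 23 CD137+ intervals a PDGFRa+ interval lay within 48 bp: those at Per1 and Vamp2, Klf13, Hif3a, Apbb2, a and Ahcy, 4930486L24Rik, and Gm16325 and 4930503B20Rik. The other 16, among them those in and upstream of Fkbp5 and in Zbtb16, Foxp1 and Tenm4, had none. The table names CD137+ as the library with the highest value at 5 of the 7 sites. PDGFRa+ was named at the other 2, with 42 against 28 at 4930486L24Rik and 65 in both at Apbb2. The median CD137+ value was 52 at the 7 shared sites and 41.25 at the 16 others. The intervals of each library were numbered by chromosome name and position. Up to and including Klf13, the last shared site, the numbers stood for 32 CD137+ and 16 PDGFRa+ intervals if each series began at 0. With 1 library per cell type, no test of these differences was possible.

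**Figure D2:**
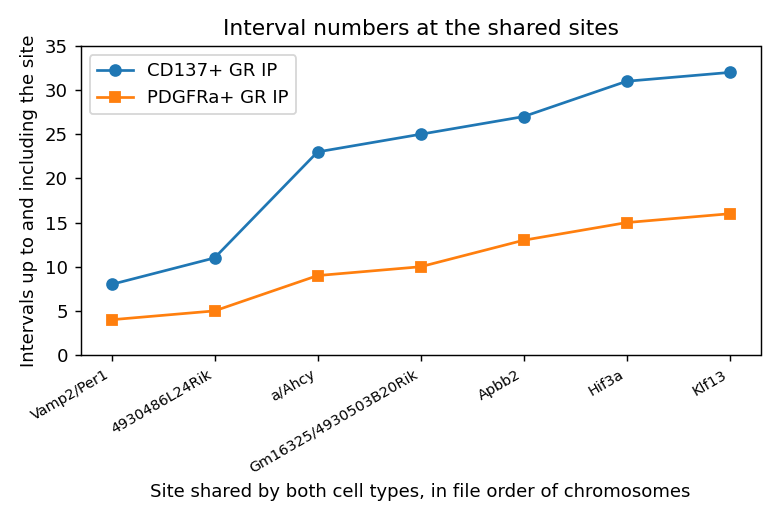
Number of GR intervals up to and including each of the 7 sites shared by both cell types (y axis), in the order of chromosome name and position (x axis), for the CD137+ and PDGFRa+ immunoprecipitates in the CD137+ table. At the last site, Klf13, the numbers were 32 for CD137+ and 16 for PDGFRa+.

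Of the 23 CD137+ intervals, 5 had a peak of the separate PDGFRa+ list within 500 bp at the same distance from the same gene. These were Tns1 (score 77), Klf13 (77, listed under its neighbour E030018B13Rik), Apbb2 (60), Zhx3 (40) and Per1 (38), and the positions differed by 10 to 82 bp. Random placements along the same chromosomes shared a mean of 0.191 sites and at most 3, and 0 of 10000 placements shared as many. These placements were not limited to genes, whereas the intervals were listed by gene, so sharing of placements near genes was not measured. The median score of the 5 peaks was 60, against 33 in the whole list, and 6 of 10000 random draws of as many peaks had a median as high. Klf13, Apbb2 and Per1 were thus found in the CD137+ intervals, the PDGFRa+ intervals and the PDGFRa+ list. The PDGFRa+ intervals and list come from the same immunoprecipitate, so they are not separate evidence of binding. Tns1 and Zhx3 had a listed peak and no PDGFRa+ interval, and the other 4 sites with a PDGFRa+ interval had no listed peak by this rule. Hif3a, among these, has a listed intron peak measured from another start site, so the rule can miss a shared site. With peaks of score 50 or more, 3 sites were shared.

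In the PDGFRa+ list, Tead1, the transcription factor gene named in the title, had 3 peaks, all in introns. The strongest, with a score of 49, lay 808 bp from the start site in intron 1 of 12 (chromosome 7, 119823570 to 119823715 as deposited, on a build other than GRCm38). A peak with a score of 26 lay in the same intron, 5078 bp from that start site. The third, with a score of 33 and starting at 119922335 as deposited, lay in intron 1 of 10 of another transcript. Its distance of 19509 bp is from another Tead1 start site, so it lay much farther from the strongest peak. Pdgfra had a promoter peak with a score of 42, 911 bp upstream of its start site (chromosome 5, 75551208 to 75551353 as deposited). Nr3c1, the gene of GR itself, was the nearest gene of 4 peaks with scores of 49, 38, 30 and 25, the strongest in intergenic sequence. Per1 had a peak with a score of 38, 1860 bp upstream of its start site, and Zbtb16 an intron peak with a score of 38. A peak with a score of 87 lay in intron 1 of 14 of Hif3a. Fkbp5, Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, and Tnfrsf9 were the nearest gene of no peak. A peak inside a gene can be listed under a neighbour, as at Klf13. The nearest gene to Fkbp5 with a peak lay 33537 bp away, so a peak within Fkbp5 is not excluded. The median score of the list was 33, and 5205 of its peaks scored 33 or less.

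Genes of adipose progenitors and of adipogenesis had a PDGFRa+ peak more often than length-matched random lists, in which peaks were counted for the nearest gene. Adipose progenitor markers had a peak in 11 of 22 genes against 4.71 in random lists (percentile 99.8), with the collagen gene Col1a2 at a score of 58, Cd24a and Lum at 49 and Pdgfra at 42. Adipogenic transcription factors had a peak in 11 of 20 genes against 6.12 (percentile 99.3). Nfia led them with 7 peaks and a highest score of 67, followed by Cebpd, Klf4 and Klf5 at 49, while Pparg, Cebpa and Cebpb had none. The Hippo and TEAD list, the growth control pathway in which Tead1 acts, had a peak in 14 of 28 genes against 8.03 (percentile 99.4). The kinase gene Stk3 scored 61, and Tead1, Ccn1, Vgll3, Yap1 and Ccn2 tied at 49, the last 2 named after their values were seen. Insulin and IGF signalling had a peak in 13 of 22 genes against 6.93 (percentile 99.6), with Igfbp3 at 59, Grb10 and Tbc1d4 at 49 and Foxo3 at 41. Inflammatory genes had a peak in 9 of 22 against 4.34 (percentile 99.0), with Il6 and Nos2 at 58, Ccl2 at 49 and Tlr4 at 41. These 5 of the 19 lists were at or above percentile 97.5. Here and below, the nearest gene can lie far from its peak. The strongest peaks of Klf4 and Klf5 lay at -498860 and 316437 bp from the start site, negative values being upstream. Those of Col1a2, Igfbp3 and Tlr4 lay at -131517, -596570 and 381143 bp. Mesothelial markers, which belong to another cell type of adipose tissue, had a peak in 6 of 13 genes, at percentile 96.0. They stood at 98.4 with matching on gene territory and at 97.9 with peaks within 100 kb.

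Of all protein-coding genes, 3.54% had a PDGFRa+ peak within 3 kb of a start site. With peaks within 3 kb of a start site, the inflammatory list was the single list at or above percentile 97.5, with 4 of 22 genes and percentile 99.7. Ccl2, a chemokine gene, was among them. Under the same rule none of the 20 adipogenic transcription factors had a peak, against 0.681 in random lists, too few to rank the list. With a score of 50 or more, 0 of the 19 lists reached percentile 97.5, in 924 peaks. With peaks within 100 kb, the adipogenic list stood at percentile 69.1 and the insulin and IGF list at 90.9. Without matching on length the inflammatory list stood at 96.5. Percentiles describe this library and are not p-values, since genes are not replicates.

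The glucocorticoid response list had a PDGFRa+ peak in 11 of 30 genes against 6.69 in random lists, below the threshold at percentile 96.5. With peaks within 100 kb it stood at percentile 98.6. Its strongest members were Bcl6, a transcriptional repressor gene, with a score of 67 in its 5' UTR, 693 bp from the start site, the kinase gene Sgk1 and Nr3c1 at 49, and Glul, the gene of glutamine synthetase, at 41. Genes of the extracellular matrix and TGF-beta signalling had a peak in 11 of 24 (percentile 97.05), with Tgfb3 and Timp3 at 49 and Tgfbr1 and Lox at 33. That list stood at 97.7 with matching on territory and at 99.3 without matching. Wnt signalling had a peak in 10 of 24 genes (percentile 94.0, and 97.6 without matching), with Fzd8 at 66, Fzd1 at 48 and Wnt10a at 41. The strongest Fzd8 peak lay at -449003 bp from the start site. Axin2 scored 199 at a peak annotated to rRNA repeat sequence. Genes of lipid synthesis and lipolysis had a peak in 10 of 28 (percentile 91.7). Abhd5, the activator of adipose triglyceride lipase, scored 58, Mgll and Gpam 49, and Elovl5 49 at its promoter. Genes of DNA methylation had a peak in 7 of 20 (percentile 85.2), with Tet1 at 49, Mbd2 at 45, Dnmt1 at 38 and Dnmt3b at 33.

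White adipocyte markers, thermogenic genes and clock genes stood between percentiles 30.7 and 67.9. White adipocyte markers had a peak in 4 of 18 genes (percentile 63.0), namely Acvr1c at 49, Lep at 41 and Lpl and Npr3 at 33. Adipoq, Fabp4 and Plin1 had none. Thermogenic and beige fat genes had a peak in 5 of 20 (percentile 30.7), with Ppargc1a and Zic1 at 58 and Dio2 and Tbx1 at 49, and without one at Ucp1 or Prdm16. The strongest peaks of Ppargc1a and Zic1 lay at 444609 and 174605 bp from the start site. Clock genes had a peak in 6 of 19 (percentile 67.9), with Nfil3 at 41, Per1 at 38 and Arntl and Rora at 33.

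**Figure D3:**
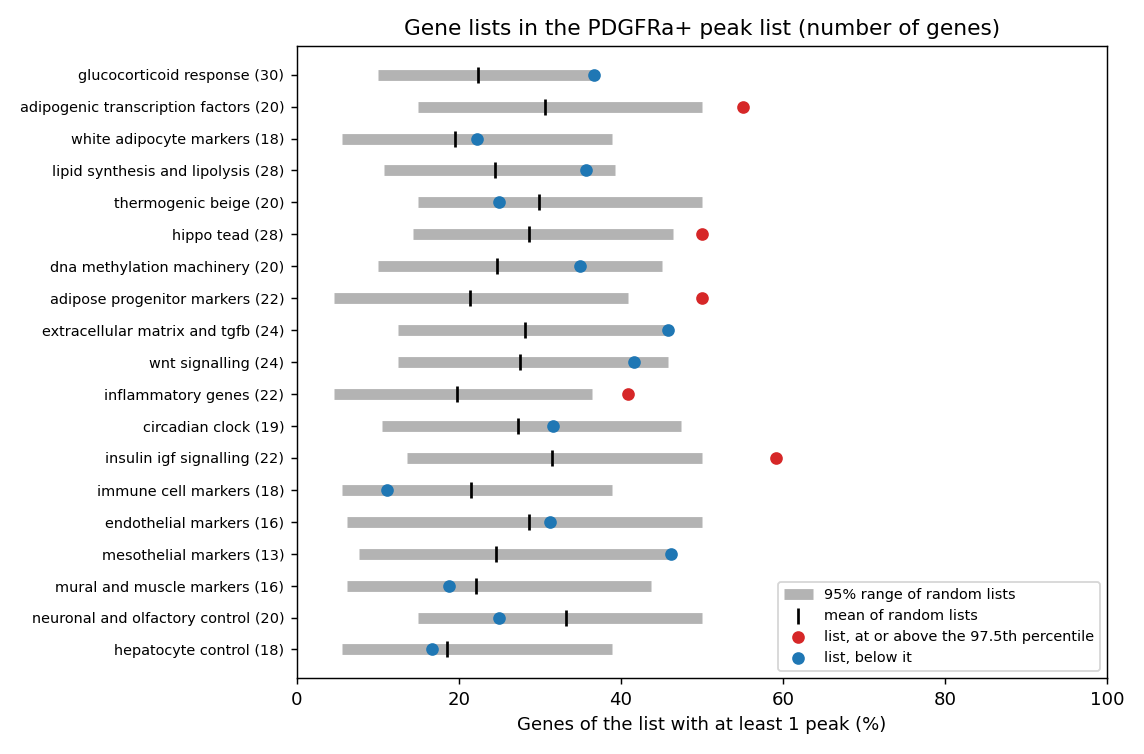
Percent of the genes of each list with at least 1 peak in the PDGFRa+ GR list (x axis), for the 19 lists with their numbers of genes (y axis). Points are the lists, bars the 95% range and ticks the mean of 10000 random lists matched on gene length; 5 lists (red) are at or above percentile 97.5.

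PDGFRa+ peaks lay mainly away from promoters. Of the 10402 peaks, 56.3% were intergenic (95% Wilson interval 55.3 to 57.2) and 37.3% in introns (36.4 to 38.2). Promoters held 2.50% (2.22 to 2.82), exons 1.26% and transcription end sites 1.08%. Within 1 kb of a start site lay 4.35% of the peaks (3.97 to 4.75), and the median distance to a start site was 47254.5 bp. Intervals cover counting error only. No genome sequence was used, so the shares were not set against random windows, and a preference for or against promoters was not tested. Among the 924 peaks with a score of 50 or more, 63.7% were intergenic (60.6 to 66.8).

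Many of the highest scores of the PDGFRa+ list stood at repeated sequence. The peaks nearest to Rab10os, Mir101c and Lrrc4c, with scores of 43344, 22731 and 21314, were all annotated to the satellite repeat GSAT_MM. Counting 1 peak per gene and leaving out predicted genes, the genes that followed were Dtnbp1 (493, rRNA repeat), Cr2 (413, outside annotated repeats), Filip1l (296, rRNA repeat), Cldn34d (265, satellite), Hic2 (213, rRNA repeat), Poll (201, simple repeat) and Axin2 (199, rRNA repeat). Astx5 (197) and Vmn2r-ps159 (190) were nearest to peaks in LINE elements and Drosha (192) to a peak in an LTR element. Timm8a1 (190) was nearest to an rRNA repeat, and Satl1 (185) held an intron peak outside annotated repeats. Satellite, rRNA, simple repeat and low complexity sequence held 42 of the 100 highest scores (95% Wilson interval 32.8 to 51.8%). In the remaining 10302 peaks it held 2.03% (1.77 to 2.32). Without these peaks the highest score was 1115.

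**Figure D4:**
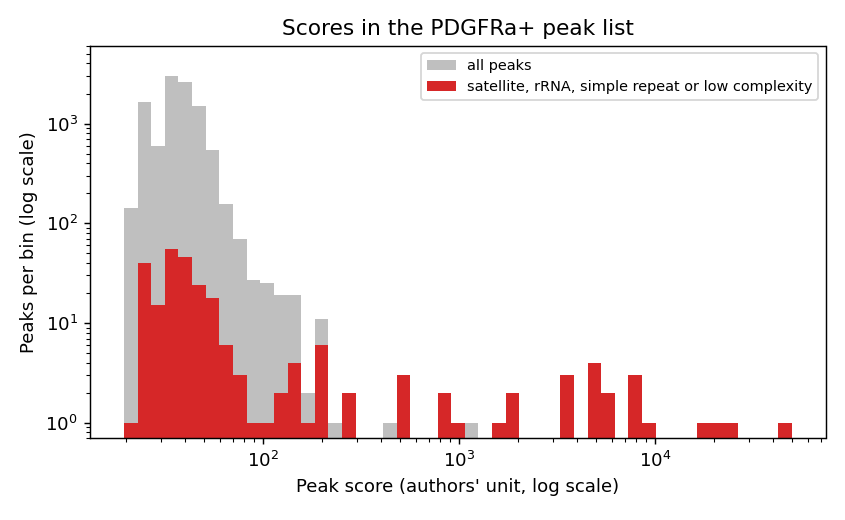
Number of peaks per bin (y axis, log scale) by peak score in the authors' unit (x axis, log scale) in the PDGFRa+ list, for all 10402 peaks (grey) and for the 251 annotated to satellite, rRNA, simple repeat or low complexity sequence (red). Outside these classes the highest score is 1115, and the median of all peaks is 33.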

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

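The alternatives with a minimum score of 50, a 100 kb limit, matching on territory, removal of repeat peaks and a 200 bp window were chosen after the data were seen; the others had been planned. A score of at least 50 left 924 of 10402 peaks, 3 of 5 shared sites, 63.7% intergenic peaks and 0 of 5 gene lists at or above percentile 97.5; this setting also leaves fewer peaks for each list. A window of 3 kb in place of 1 kb held 8.83% of peaks. With peaks within 3 kb, 1 list was at or above percentile 97.5, the inflammatory list, and the adipogenic transcription factors stood at percentile 25.05 with 0 genes against 0.681, a count too small to show a reversal. The CD137+ intervals were given no stricter setting. Restriction to autosomes and X gave 10374 peaks and removal of repeat peaks 10151, and the number of shared sites was 5 with windows of 200 bp and of 1 kb. The number of lists was 6 without matching (4 of the 5 kept), 5 within 100 kb (3 kept), 7 with matching on territory (all 5 kept) and 5 without repeat peaks (all 5 kept). The cause of these changes was not tested. Not run were thresholds on q and enrichment and q as a measure of strength, which the list does not hold, overlap by shared length and a new annotation, since the builds differ, and the motif search with its alternatives. No paired analysis was possible because each group has 1 library, and no replicate could be left out. Depth is unknown, so a missing peak does not show a missing site.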

Other observations

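The tests of table size and of repeats were chosen after the results were seen, and those with matching on territory, with peaks within 100 kb and by score class use settings chosen after the data were seen. Marker lists of other cell types stayed below percentile 97.5 in the PDGFRa+ list with all peaks and matching on gene length. Mesothelial markers came nearest, with a peak in 6 of 13 genes (percentile 96.0, 98.4 with matching on territory and 97.9 with peaks within 100 kb), with Gpm6a at a score of 59, Krt18 and Rspo1 at 49 and Wt1 at 41. Endothelial markers had a peak in 5 of 16 (percentile 60.1), with Sox17 at 38, Emcn and Erg at 33 and Tie1 at 28. Mural and muscle markers had a peak in 3 of 16 (percentile 39.3), namely Mcam at 58, Cspg4 at 41 and Rgs5 at 33. Immune cell markers had a peak in 2 of 18 (percentile 14.0), Ncr1 at 49 and Cd8a at 41. The control lists of neuronal and olfactory genes (5 of 20, percentile 19.2) and of hepatocyte genes (3 of 18, percentile 44.3) included Syt1 at 58, Neurod1 at 41 and Camk2a at 33, and Serpina1a and Cps1 at 41 and Ahsg at 40, respectively.

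On the X chromosome, 116 of 236 PDGFRa+ peaks lay between 120 and 123 Mb as deposited, and 21 of the 100 highest scores were among them. Peaks numbered 1.42 per Mb on X, 0.733 per Mb on X without that stretch, and 4.11 per Mb on the autosomes, whose range was 3.50 to 4.48. Y held 28 peaks. Dense stretches were not limited to X. Chromosome 4 held 38 peaks between 146 and 147 Mb, and chromosome 5 held 22 from 94 to 95 Mb and 23 from 95 to 96 Mb. Chromosome 9 held 24 between 3 and 4 Mb, with a median score of 2747.5. Chosen after its values were seen, Foxp1 was the nearest gene of 6 PDGFRa+ peaks, as was Tenm4. By the distance rule, none of them was counted as shared with the CD137+ interval at the same gene. That rule can miss a site measured from another start site. However, all 6 Tenm4 peaks were intergenic and from 5511 to 1125554 bp upstream, while the CD137+ interval lay 502419 bp into the gene.

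The PDGFRa+ list held 10402 peaks and the CD137+ gene table listed 23 intervals. The interval numbers in the CD137+ table run beyond its entries, so they were read as a count of each library's intervals, listed or not. If the numbers began at 0, up to the last shared site, Klf13, there were 16 PDGFRa+ and 32 CD137+ intervals. Up to that site the PDGFRa+ library thus did not have more intervals than the CD137+ library. The counts come from 1 library per cell type, with unknown depth and calling threshold. They therefore cannot decide whether PDGFRa+ cells had more GR sites. The same PDGFRa+ immunoprecipitate had 16 intervals up to that site in the CD137+ table and 10402 peaks over the whole genome in the PDGFRa+ list. Chromosome 1 alone, the first in the numbering, held 839 of those peaks. If the numbers count intervals, the 2 tables were therefore called or filtered differently, and their sizes do not compare the cell types. The depth and enrichment of the libraries were not tested and stay open. So does any difference between the cell types, a larger number of PDGFRa+ sites included.

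In the PDGFRa+ list, 5 gene lists of progenitor, adipogenic, Hippo, insulin and inflammatory genes were at or above percentile 97.5. Wide territories around these genes were weighed, since the nearest-gene rule gives such genes more peaks. Of the 5 lists, 5 stayed at or above the threshold when random lists had matched territories. Territory was measured from gene bodies and gaps, while peaks were assigned by start site, so the match is approximate. With peaks within 100 kb, 3 of the 5 were kept. The adipogenic list then stood at percentile 69.1 and the insulin list at 90.9, so wide territories stay open for these lists. Random placement of weak peaks was weighed too: with scores of 33 or less, 79 of the 292 genes of the adipose and signalling lists had a peak against 52.6 in territory-matched lists, at percentile 100, while 14 of 101 genes of the other cell type and control lists did, at percentile 31.4. The 2 sets of lists stood at percentiles 99.3 and 63.0 with scores of 34 to 49, and with scores of 50 or more at 79.4 (12 of 292 against 9.57, range 4 to 16) and 79.3 (4 of 101 against 2.71, range 0 to 6), counts too small to decide. A hypothesis is that weak peaks may hold accessible or GR-bound chromatin of these cells; the input was not analysed here, so open chromatin and GR binding stay open alike.

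Many of the highest PDGFRa+ scores stood at satellite and rRNA repeats. Reads from many repeat copies piling up on the few copies in the assembly could give such scores, but the 42 of the 100 highest scores in these repeat classes are the pattern itself and decide nothing. Peaks of the GSAT_MM satellite near Rab10os, Mir101c and Lrrc4c led the list. Whether the same positions were high in the input was not tested. No biological explanation was tested.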
